A study of Mus musculus with 9 samples.

How the data were processed

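The study measured gene expression by RNA sequencing in islets of 4-week-old mice, 4 control and 3 labelled knockout, and Glis3 binding by chromatin immunoprecipitation in islets of 8-week-old Glis3-eGFP mice. Per the labels' design text, the RNA libraries came from separate mice. Groups and replicate numbers were taken from the labels. The input library of the binding experiment was not analysed here.

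The expression values were whole-number counts per gene, deposited without normalisation, with gene symbols, Entrez identifiers and mm10 coordinates per the file headers. STAR 2.5 and featureCounts 1.5.0-p1 of Subread, with build mm10, and DESeq2 are named per the submitters' processing notes, and the settings, the strand option and the annotation were not given in the sources used here. The table held 25611 rows, of which 988 repeated a symbol already present and were kept as separate genes. The peaks were 200 bp intervals deposited by the authors with no score. Cutadapt 1.2.1, Bowtie 1.2, Picard 1.110, HOMER 4.9.1 and bedtools 2.24.0 are named per the submitters' processing notes, without roles or thresholds, and how the input library was used was not given in the sources used here.

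From the counts, genes were kept with filterByExpr by group, library sizes were scaled with TMM factors, and the groups were compared with edgeR 4.0.16 (quasi-likelihood F test with robust dispersions, R 4.3.3). P-values were adjusted over all 14529 tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are labelled knockout over control. Each SE is the absolute log2 fold change divided by the square root of its F statistic. Levels are TMM-normalised CPM, counts scaled to a library of 1e6 counts, given as mean ± SD. Total counts per library ran from 12099365 to 48054551. Counting intervals and the floor of 3 counts cover counting error only, since the reads carry no molecular identifiers. No 2 libraries of a group were copies: over genes with at least 10 counts in a pair, the chi-square per degree of freedom was 23.4 to 95.4.

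In the 14529 tested genes, 3864 (26.6%) had no overlap of CPM between the groups, against 5.71% by chance for 4 against 3 libraries. The fit was tested on simulated counts with the real library sizes, over 14114 genes. Of these, 64 were changed 1.5-fold, 65 were changed 2-fold and 65 were changed 4-fold. It recovered 12.5% of genes changed 1.5-fold, 44.6% changed 2-fold and 86.2% changed 4-fold in the comparison of labelled knockout against control, and 5.1% of its 98 calls were false. The Fisher's exact test used for peaks was run on independent simulated yes or no flags with an odds ratio of 3 and gave 2.97. No peak positions entered that check.

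A set of 26 gene lists (islet cell types, other cell types of the pancreas, and pathways) was fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over the lists. Members were also counted with p adjusted over the list alone. Named genes followed a rule fixed at the same time: Glis3, the 12 largest falls and 12 largest rises among called genes with at least 1 CPM on average and no overlap between groups (predicted genes left out), up to 4 called members per list with the smallest p, the islet hormone and beta cell genes Ins1, Ins2, Gcg, Sst, Ppy, Slc2a2, Mafa, Pdx1, Nkx6-1, Ucn3 and G6pc2, and the earlier described Glis3 targets. Further list members are named as examples and were chosen after their values were seen, and the genes named for a peak or its absence were chosen among the named genes. The parts of the rule that rank peaks by score were not applied, because the peaks had no score.

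Peak midpoints were set against the 5′ end of each gene span in the count table, 1 per gene, since no transcript or exon annotation was used here. Genes with a peak within 10 kb were compared with all other tested genes by 2-sided Fisher's exact test and by logistic regression. The regression covariate was log2(mean CPM + 0.5), with the mean over all libraries (mean log2 CPM in the peak results) or over the controls (control log2 CPM). As a background, the peaks were shifted along their chromosomes 100 times at random. Motifs were not searched, since no genome sequence was used here.

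Alternatives were RLE factors, library size alone, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, leaving out each library, the acinar marker mean as a covariate, leaving out the 10 most abundant genes, an adjusted p under 0.01, a glmTreat test against a 1.5-fold change, an estimated correlation in camera, and windows of 1, 50 and 100 kb or the nearest gene for peaks. A covariate for Xist, a fit of the 4 libraries with Xist reads, control log2 CPM as the covariate for distal peaks, and library size alone with the 10 most abundant genes left out (Glis3 only) were added after seeing the data. Figures were drawn with matplotlib 3.10.9.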

Results

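Gene expression was measured by RNA sequencing in pancreatic islets of 4-week-old mice, and binding of the transcription factor Glis3 was mapped by chromatin immunoprecipitation in islets of 8-week-old mice. Glis3 is a Krüppel-like zinc finger protein of the pancreas. The RNA comparison asks which islet genes change when Glis3 is deleted in the pancreatic lineage marked by Pdx1. The RNA set held 7 libraries, 4 from control mice with the conditional allele alone (Glis3fl/fl) and 3 from mice labelled knockout. The mice labelled knockout also carried the Pdx1-Cre driver. No group carried the driver without the conditional allele, so effects of the driver cannot be told apart from those of the deletion. Total counts ran from 18297697 to 48054551 per control library and from 12099365 to 22578480 per labelled knockout library. The binding set was 1 list of 21254 peaks from Glis3-eGFP mice, whose tagged protein was pulled down with an antibody against GFP, so the binding data had no replicate.

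The targeted gene was not lower in the libraries labelled knockout. Glis3 (chromosome 19, 28258851 to 28680077, minus strand, mm10) stood at 37.8 ± 6.95 CPM (SD, n = 4) in controls and at 54.2 ± 3.11 CPM (SD, n = 3) in the libraries labelled knockout. The values were 39.53, 46.77, 31.23 and 33.55 CPM in controls 1 to 4 and 52.05, 52.74 and 57.75 CPM in labelled knockouts 1 to 3. The log2 fold change was 0.52 (SE 0.14), with an adjusted p of 0.0257 (edgeR quasi-likelihood test, Benjamini-Hochberg). A count over the whole gene does not separate reads of the deleted exons from the rest, so it leaves the deletion unchecked, and the group is called labelled knockout throughout. Without control 3 the log2 change was 0.42 (edgeR adjusted p = 0.0945), without control 4 it was 0.45 (0.085), without labelled knockout 1 it was 0.54 (0.0501) and without labelled knockout 3 it was 0.44 (0.117). Over all alternatives the adjusted p of Glis3 ran from 0.00948 to 0.372.

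Both insulin genes fell, while other islet hormones went separate ways. Ins2 took 25.4 ± 2.54% of all counts in controls (SD, n = 4) and 9.58 ± 2.51% in the libraries labelled knockout (SD, n = 3). After normalisation Ins2 was 3.02-fold lower (log2 −1.59, SE 0.23, edgeR adjusted p = 4.0e-04) and Ins1 was 2.47-fold lower (log2 −1.30, SE 0.28, edgeR adjusted p = 0.00751). These genes are close copies of each other, so reads may have been split between them. Ppy, the pancreatic polypeptide gene, fell from 6330 ± 2197 to 478 ± 172 CPM (log2 −3.73, SE 0.42), and the related hormone gene Pyy fell by 1.43 on the log2 scale (SE 0.18). Iapp, which encodes the amylin that beta cells secrete with insulin, rose from 23991 ± 3217 to 85883 ± 13287 CPM (log2 1.84, SE 0.16, edgeR adjusted p = 3.8e-06). Glucagon (Gcg, log2 −0.32, SE 0.20, edgeR adjusted p = 0.343) and somatostatin (Sst, log2 0.12, SE 0.16, edgeR adjusted p = 0.677) did not pass the test.

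**Figure D1:**
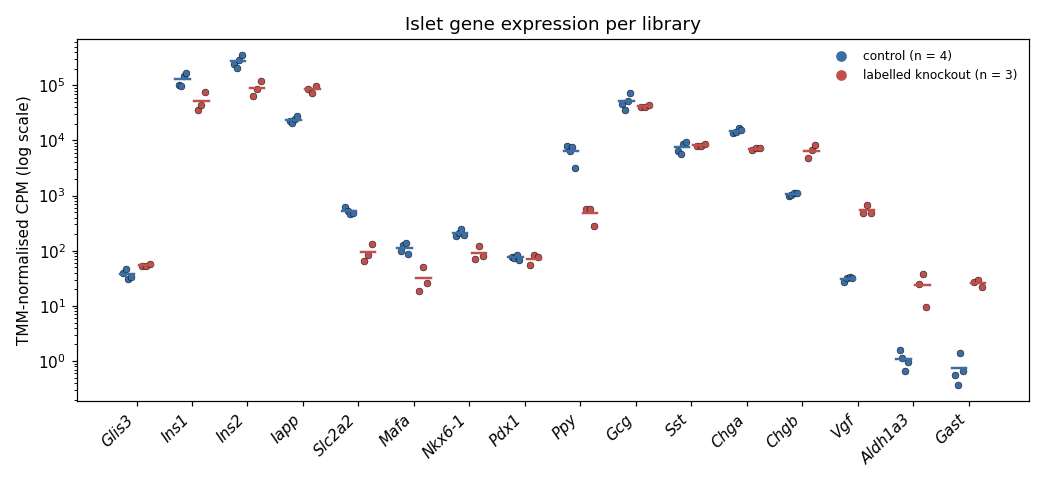
TMM-normalised CPM of 16 islet genes on a log axis, 1 point per library, with short lines at the means of 4 control and 3 labelled knockout libraries. Ins1, Ins2, Slc2a2, Mafa, Nkx6-1, Ppy and Chga lie lower in every labelled knockout library than in any control, and Iapp, Chgb, Vgf, Aldh1a3, Gast and Glis3 lie higher.

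Across all genes, 14529 were tested, of which 763 were lower and 1268 higher in the libraries labelled knockout at an edgeR adjusted p under 0.05. Among these, 218 fell and 597 rose at least 2-fold, and 53 fell and 241 rose at least 4-fold. The largest falls under the naming rule were in Mcoln3, a cation channel gene (2.46 ± 0.51 to 0.0148 ± 0.0256 CPM; 1 count in total in the labelled knockouts), Kcnj12, an inward rectifier potassium channel gene (12.3 ± 1.94 to 0.234 ± 0.244 CPM), and the genes Lingo3, Cyp4f39, T2, Sytl3 and Epha8. The ratio of Mcoln3 counts, labelled knockout over control, was 0.00666, with a 95% counting interval from 0.000168 to 0.0374. Gad1, which encodes the GABA-producing glutamate decarboxylase, fell from 84.6 ± 13.4 to 5.64 ± 3.92 CPM (log2 −3.86, SE 0.45), and Ppp1r17, Cd79a, Ppy and Plek2 completed the 12. Cyp4f39 lost its call without labelled knockout 2 (edgeR adjusted p = 0.0585; 2.9e-05 to 0.0585 over the alternatives). Plek2 lost it without control 3, control 4, labelled knockout 1 or labelled knockout 2 (edgeR adjusted p from 0.0514 to 0.0781 there; 0.000543 to 0.134 over the alternatives).

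Several genes near absent from control islets rose most. Cck, the cholecystokinin gene, went from 0.164 ± 0.163 to 125 ± 37.7 CPM (log2 9.60, SE 0.38, edgeR adjusted p = 7.7e-08). Klhl1 had no count in any control library and 3.4 ± 0.8 CPM in the labelled knockouts, at least 138-fold higher against a floor of 3 counts over the control group. Krt27, a keratin gene, had 1 control count in total and 374 in the labelled knockouts, a ratio of 742 with a 95% counting interval from 132 to 29400. Prss1, a trypsinogen gene, rose from 0.347 ± 0.249 to 165 ± 83.2 CPM, and Csmd3, Adtrp, Csn3, Tm4sf20, Nog and Sval2 rose by log2 values of 6.79 to 8.19. The stomach genes Pgc (pepsinogen C, 2 control counts, a ratio of 962 with a counting interval from 266 to 7960) and Gkn3 (log2 8.25) were also among the 12. Labelled knockout 1 carried most of this rise, as labelled knockouts 1 to 3 had 58.58, 0.9071 and 7.086 CPM of Pgc and 53.68, 5.572 and 11.25 CPM of Gkn3. Without it the log2 change fell from 9.95 to 7.50 for Pgc and from 8.25 to 6.73 for Gkn3, and without control 1 that of Pgc was 12.08. Pgc lost its call without any 1 of the 4 controls or without labelled knockout 3, at edgeR adjusted p from 0.0608 to 0.327, and Gkn3 without control 1, at 0.0524. Over the alternatives these p-values ran from 1.1e-07 to 0.448 for Pgc and from 1.25e-08 to 0.26 for Gkn3.

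**Figure D2:**
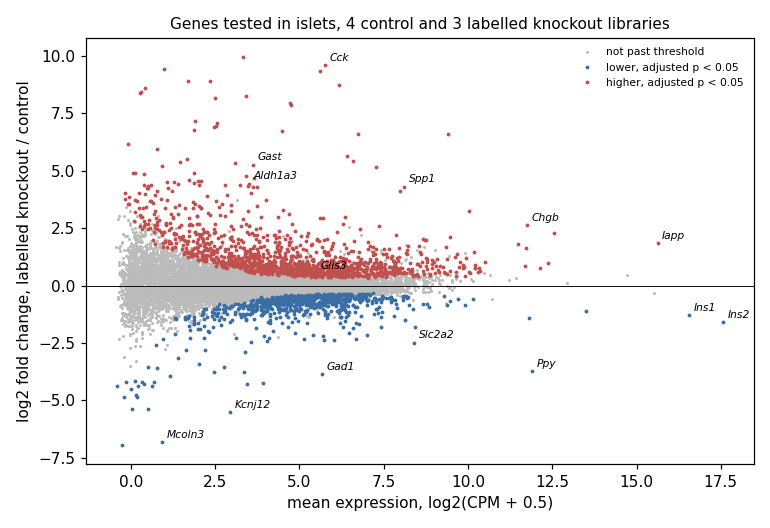
Log2 fold change of each of 14529 tested genes against log2(mean CPM + 0.5), with the mean over the 7 libraries. The 763 lower genes are in blue, the 1268 higher genes in red and the rest in grey. Ins2 and Ins1 are the most abundant genes that fell, and Iapp is the most abundant that rose.

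Genes of beta cell identity and glucose sensing fell more often than they rose. Of 27 measured members 12 fell, 5 rose and 10 did not pass, or 16 lower and 6 higher adjusted over the list alone. Slc2a2, the glucose transporter GLUT2, fell from 524 ± 68.6 to 93.2 ± 35.7 CPM (5.62-fold lower, log2 −2.49, SE 0.23, edgeR adjusted p = 8.4e-06). Trpm5 (log2 −2.31), Sytl4 (−1.38), Gipr (−1.12), Prlr (−1.01) and the zinc transporter gene Slc30a8 (−0.95) also fell. Besides Iapp, Npy (log2 2.03), Pcsk1 (1.47), Tmem27 (0.88) and the sulfonylurea receptor gene Abcc8 (0.55) rose. Ucn3 (log2 −0.78, SE 0.25, edgeR adjusted p = 0.0642) and G6pc2 (log2 −0.58, SE 0.21, edgeR adjusted p = 0.093) missed the threshold. Ucn3 passed it without control 1 (edgeR adjusted p = 0.0281), control 2 (0.0497) or labelled knockout 3 (0.0207), and G6pc2 without control 3 (0.0374), with ranges over the alternatives of 0.00257 to 0.213 and 0.0156 to 0.437. The list as a whole was lower by camera (adjusted p = 0.00276; adjusted p = 0.434 with an estimated correlation).

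Islet transcription factors moved in both directions, with 4 of 26 lower, 4 higher and 18 not passing (camera adjusted p = 0.399; 7 lower and 4 higher adjusted over the list alone). Nkx6-1 fell from 211 ± 30.3 to 90.8 ± 27.3 CPM (log2 −1.21, SE 0.18, edgeR adjusted p = 5.4e-04), and Mafa fell from 112 ± 23.9 to 32.1 ± 17.3 CPM (log2 −1.79, SE 0.35, edgeR adjusted p = 0.0135). Neurod1 (log2 −0.58) fell less, while the estrogen receptor gene Esr1 (4.57), Esrrg (1.13), Isl1 (0.73) and Rfx6 (0.45) rose. Pdx1 stood at 75.5 ± 6.92 CPM in controls and 71.1 ± 14.2 CPM in labelled knockouts (log2 −0.08, SE 0.14, edgeR adjusted p = 0.753), a difference within the spread of the libraries and of opposite sign under scaling by library size alone (0.081) or without labelled knockout 1 (0.064). Mafa missed the threshold without control 1 (edgeR adjusted p = 0.0503) and Esrrg without labelled knockout 2 (0.0639), with ranges over the alternatives of 3.6e-05 to 0.076 and 0.00121 to 0.153.

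Of 5 genes described earlier as Glis3 targets, 3 fell and 2 did not pass, or 4 lower adjusted over the list alone (camera adjusted p = 0.0285, or 0.0746 with no filter on low counts, and 0.000281 to 0.0746 over the alternatives; adjusted p = 0.457 with an estimated correlation). Ins1, Ins2 and the cyclin gene Ccnd2 (491 ± 18.6 to 286 ± 27.6 CPM, log2 −0.78, SE 0.12, edgeR adjusted p = 6.1e-04) were the members that fell. Neurog3 had 11.9 ± 2.79 CPM in controls and 2.59 ± 2.65 CPM in labelled knockouts (log2 −2.13, SE 0.78, edgeR adjusted p = 0.126), and the splicing factor gene Srsf6 was level (log2 −0.05, SE 0.11, edgeR adjusted p = 0.838; 0.13 scaled by library size alone). Neurog3 stood at 0.07425, 5.356 and 2.347 CPM in labelled knockouts 1 to 3. It passed the threshold without labelled knockout 1 (log2 −1.62, edgeR adjusted p = 0.00973) or labelled knockout 2 (log2 −3.13, 0.0364), with a range over the alternatives of 0.00973 to 0.367.

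Genes of hormone processing and granule exocytosis rose more often than they fell, with 13 of 32 higher, 4 lower and 15 not passing. Vgf, a granule neuropeptide precursor, rose from 31.3 ± 2.57 to 546 ± 123 CPM (log2 4.13, SE 0.16, edgeR adjusted p = 6.6e-09). Chromogranin B (Chgb) rose from 1062 ± 67.3 to 6548 ± 1656 CPM (log2 2.62, SE 0.16, edgeR adjusted p = 3.7e-07), and Scg3 (log2 1.82), Pcsk1 (1.47), Ptprn (1.45) and Pam (1.27) also rose. Chromogranin A (Chga, log2 −1.11), Sytl4 and Slc30a8 were among those that fell. The list was higher by camera (adjusted p = 0.0245; adjusted p = 0.434 with an estimated correlation), with 13 higher and 5 lower adjusted over the list alone.

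Markers of beta cell dedifferentiation and hyperglycaemia rose in 7 of 12 members and fell in none, with 5 not passing. Gast, the gastrin gene, rose from 0.749 ± 0.451 to 26.3 ± 3.73 CPM (log2 5.27, SE 0.33, edgeR adjusted p = 4.3e-07), and the retinaldehyde dehydrogenase gene Aldh1a3 rose from 1.08 ± 0.38 to 24.1 ± 14.2 CPM (log2 4.43, SE 0.43, edgeR adjusted p = 2.7e-05). Slc5a10 (log2 3.55), Serpina7 (2.11), Txnip (2.01) and Cd81 (1.06) rose with Cck. Adjusted over the list alone, 8 were higher and 2 lower. The 2 lower were Neurog3 (log2 −2.13) and Fev (−0.56), which did not pass over all genes. The camera adjusted p of the list was 5.9e-05 (adjusted p = 0.134 with an estimated correlation). Among 18 genes normally silent in beta cells, Igfbp4 (log2 1.13) and Cxcl12 (1.06) rose and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.285, fry adjusted p = 0.0136).

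Genes of cholesterol and fatty acid synthesis fell in 11 of 23 members, with 1 higher and 11 not passing. Hmgcs1 (log2 −0.97, SE 0.12), Srebf1, which encodes a transcription factor of lipid synthesis (−0.87, SE 0.14), and Insig1 (−1.13, SE 0.18) were each lower in all 3 labelled knockout libraries than in any control. Elovl6, a fatty acid elongase gene, was the member that rose (0.43). The camera adjusted p was 2.5e-06 (adjusted p = 0.434 with an estimated correlation), with 13 lower and 1 higher adjusted over the list alone. Genes of oxidative phosphorylation were higher in 6 of 28 members, lower in none and not passing in 22, led by Ndufa1 (log2 1.61, SE 0.25), Ndufb8 (0.71, SE 0.14), Ndufa4 (0.54) and Atp5o (0.52), with 11 higher adjusted over the list alone (camera adjusted p = 1.9e-04; adjusted p = 0.603 with an estimated correlation). Atp5o and Ndufa4 each lost the call without control 1, 2 or 3 or labelled knockout 1 or 3 (edgeR adjusted p from 0.0542 to 0.0827 and from 0.0734 to 0.162 there; 0.00108 to 0.154 and 0.000972 to 0.162 over the alternatives). Of 19 glycolysis genes Gapdh (log2 0.64), Pkm (0.60) and Gpi1 (0.56) rose, Aldoc fell by 1.08 and 15 did not pass (camera adjusted p = 0.399; 4 higher and 2 lower adjusted over the list alone).

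In the unfolded protein response 7 of 22 genes rose, among them Hsp90b1 (log2 0.77, SE 0.12), Pdia6 (0.86) and Pdia4 (0.60), which help proteins fold, and Edem1 (0.80), 14 did not pass, and the transcription factor gene Atf4 fell by 0.56 (SE 0.12). The list did not pass (camera adjusted p = 0.135; 7 higher and 1 lower adjusted over the list alone), but did without control 3 (camera adjusted p = 0.0346) or labelled knockout 1 (0.036), with a range over the alternatives of 0.00806 to 0.284. Pdia4 lost its call without labelled knockout 3 (edgeR adjusted p = 0.057; 0.00122 to 0.159 over the alternatives). Cell cycle genes showed 1 call each way among 29, Ccnd2 lower and Ccne1 higher (log2 1.14), and 27 did not pass (camera adjusted p = 0.45; 1 lower adjusted over the list alone). Ccne1 was not called without control 1, control 3, control 4 or labelled knockout 2 (edgeR adjusted p from 0.0636 to 0.149 there; 0.00823 to 0.285 over the alternatives). No member passed among 16 immediate early and heat shock genes (camera adjusted p = 0.601) or among 12 genes of the Gli, Glis and Hedgehog pathway (camera adjusted p = 0.746), and none did adjusted over the list alone. Of 11 genes that respond to the prolactin receptor, Wipi1 (log2 1.09) and Lrrc55 (3.48) rose, Ivd fell by 0.62 and 8 did not pass (camera adjusted p = 0.399; 3 higher and 4 lower adjusted over the list alone), and the median (−0.49) and mean (0.24) of this list differed in sign. Lrrc55 was not called without control 1, control 2 or any 1 of the labelled knockouts (edgeR adjusted p from 0.0588 to 0.0948 there; 0.00641 to 0.142 over the alternatives).

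Alpha and delta cell markers moved in both directions, and the 2 called gamma and epsilon cell markers fell. Of 14 alpha cell markers, Gc (log2 2.21, SE 0.12), Slc38a5 (2.46, SE 0.17), Ttr (1.65, SE 0.16) and Sv2b (0.95, SE 0.23) were among 5 that rose, 3 fell, among them Irx1 (−0.82) and Irx2 (−0.53), and 6 did not pass (camera adjusted p = 0.399, fry adjusted p = 0.0418; 5 higher and 4 lower adjusted over the list alone). The median of that list was −0.17 and the mean 0.29, the sign of the test. Sv2b lost its call without labelled knockout 1 (edgeR adjusted p = 0.0667; 0.00142 to 0.0723 over the alternatives). Of 11 delta cell markers Rbp4 (log2 2.12) and Ptprz1 (1.92) rose, Hadh fell by 0.67 and 8 did not pass (camera adjusted p = 0.912; 2 each way adjusted over the list alone), with the median (−0.17) and mean (−0.040) opposite in sign to the test. Of 8 gamma and epsilon cell markers Ppy and Pyy fell and 6 did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.034, fry adjusted p = 0.0117; adjusted p = 0.434 with an estimated correlation). That call was lost without control 1 (camera adjusted p = 0.0586), labelled knockout 2 (0.101) or labelled knockout 3 (0.0734), with a range over the alternatives of 0.00403 to 0.149.

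Among markers of non-endocrine cells, most did not pass as single genes. Of 34 acinar markers 2 trypsinogen family genes rose, Prss1 and Prss3, whose reads may be shared with close copies, and 32 did not pass (camera adjusted p = 4.4e-05; adjusted p = 0.603 with an estimated correlation; 2 adjusted over the list alone). The mean log2 CPM of that list was 3.37, 5.56, 3.23 and 5.71 in controls 1 to 4 and 5.25, 7.52 and 5.69 in labelled knockouts 1 to 3, so the groups overlapped. Prss3 was not called without control 2, control 3 or any 1 of the labelled knockouts (edgeR adjusted p from 0.0532 to 0.087 there; 7.6e-06 to 0.111 over the alternatives). Stromal and pericyte markers rose in 6 of 18 members and did not pass in 12, or rose in 12 adjusted over the list alone, with Dcn (log2 0.92), Col6a2 (0.85), Mgp (0.64), Rgs5 (0.61) and Sparc (0.56) among them (camera adjusted p = 1.2e-04; adjusted p = 0.434 with an estimated correlation). Rgs5 lost its call without control 3, labelled knockout 2 or labelled knockout 3 (edgeR adjusted p from 0.0535 to 0.0592 there; 0.000921 to 0.227 over the alternatives). Of 15 duct cell markers Spp1, the osteopontin gene (30.5 ± 9.92 to 598 ± 132 CPM, log2 4.29), Car2 (1.95), Ambp (1.47) and Atp1b1 (0.85) rose, Dcdc2a fell by 0.88 and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0246, or 0.162 without labelled knockout 1, and 0.0058 to 0.162 over the alternatives; adjusted p = 0.434 with an estimated correlation).

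Of 17 macrophage and myeloid markers C1qa (log2 0.72, SE 0.12) and Fcer1g (0.82, SE 0.25) rose and 15 did not pass, with 3 higher adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.603 with an estimated correlation). That call was lost without control 2 (camera adjusted p = 0.159) or labelled knockout 3 (0.254), with a range over the alternatives of 0.0027 to 0.254. Fcer1g lost its call without any 1 library other than control 4 (edgeR adjusted p from 0.0502 to 0.192 there; 0.00231 to 0.219 over the alternatives). Of 3 lymphocyte markers Cd79a, a B cell receptor subunit gene, fell 13.6-fold from 16.3 ± 2.85 CPM (log2 −3.76, SE 0.59) and 2 did not pass (1 lower adjusted over the list alone; camera adjusted p = 0.399), and the list's median (0.042) and mean (−0.94) differed in sign. No member passed among 17 endothelial (camera adjusted p = 0.32), 9 Schwann and glial (0.598) and 2 adipocyte markers (0.746), and none did adjusted over the list alone. Neither of 2 red blood cell markers passed (camera adjusted p = 0.241), though both did adjusted over the list alone, and that list passed without labelled knockout 1 (camera adjusted p = 0.0177; 0.0177 to 0.659 over the alternatives).

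**Figure D3:**
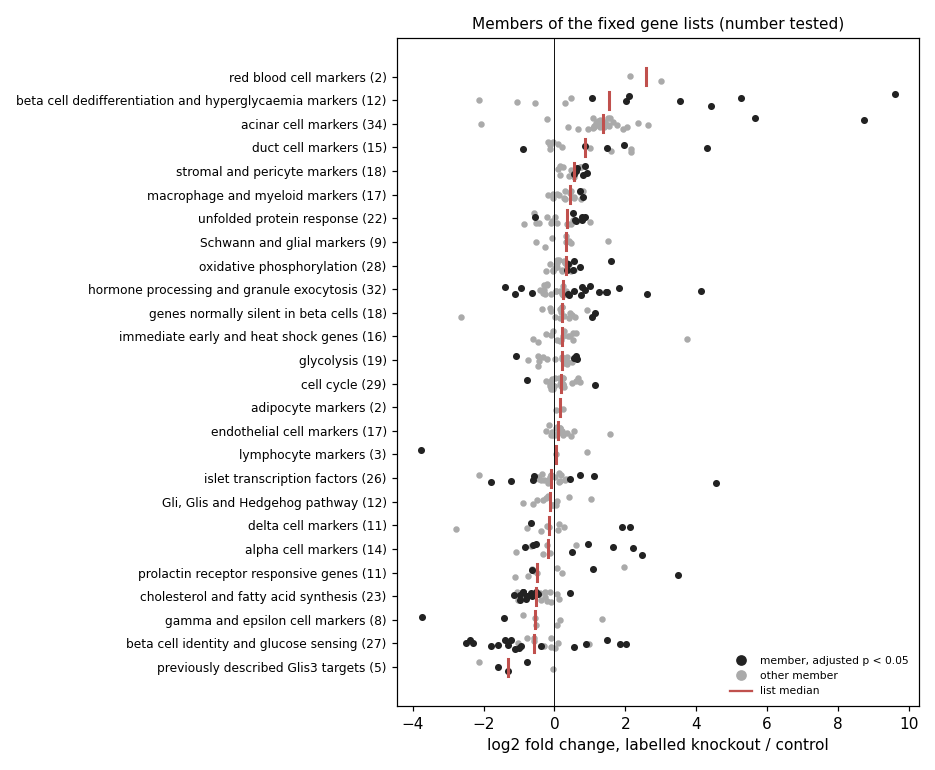
Log2 fold change (labelled knockout over control) of the members of 26 gene lists, 1 point per gene, black where the edgeR adjusted p was under 0.05, with a red line at each list's median and the number tested in brackets. Cholesterol and fatty acid synthesis has 11 of 23 members called lower, and the dedifferentiation list has 7 of 12 called higher.

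Of the 26 lists, 11 passed by camera with its preset correlation, 4 lower and 7 higher, none passed with an estimated correlation, and 10 passed by fry, which tests whether members move one way on balance. The fry calls include the alpha cell list and the list of genes normally silent in beta cells, which camera did not call, and leave out acinar, macrophage and oxidative phosphorylation genes. The libraries also split on Xist, a transcript of the inactive X chromosome. Xist stood at 235 to 270 CPM in controls 1 and 2 and labelled knockouts 1 and 2, while controls 3 and 4 and labelled knockout 3 had Y-linked reads. In the 4 libraries with Xist reads, 314 genes were lower and 734 higher, of which 919 were calls of all 7 libraries in the same direction. Ins2 (log2 −1.61), Slc2a2 (−2.99), Ppy (−3.67), Iapp (1.85), Chgb (2.49) and Vgf (4.27) were called there, and Mafa was not (−1.68, edgeR adjusted p = 0.076; 3.62e-05 to 0.076 over the alternatives). The libraries with Y-linked reads held 1 labelled knockout and were not fitted alone. With the mean log2 CPM of the acinar markers as a covariate, 334 genes were lower and 718 higher, and scaled by library size alone the counts were 324 and 1854, with the median of all genes at 0.175 (14.9% of calls lower, against 37.6%).

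Glis3-eGFP peaks lay close to the starts of expressed genes. Each peak was 200 bp wide, and 49.96% (exact binomial 95% interval 49.28 to 50.63%) had their midpoint within 1 kb of the 5′ end of a gene, against a mean of 1.9% for 100 random shifts of the peaks along their chromosomes. Within 10 kb the share was 61.67% (61.02 to 62.33%), against 16.35% for the shifts. A further 28.2% of peaks lay inside genes and 21.84% outside genes, each more than 1 kb from a 5′ end. Of the 14529 tested genes 80.49% had a peak within 10 kb, against 16.76% of the 11082 genes that were too low to test.

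Slc2a2 had a peak centred at −1689 bp from its 5′ end (chromosome 3, 28696115 to 28696314; negative is upstream), and 5 within 50 kb. Ins2 had a peak at −170 bp (chromosome 7, 142679797 to 142679996) and Ins1 had 1 at −40 bp (chromosome 19, 52264158 to 52264357). Mafa had peaks at 695 and −8354 bp, and Nkx6-1 had peaks at 428 and 8348 bp. Glis3 itself had a peak at 204 bp (chromosome 19, 28679774 to 28679973). Pdx1 (−1866 bp), Iapp (−102 bp), Chgb (257 bp) and Kcnj12 (−154 bp) also had a peak within 10 kb. Cck, Klhl1, Prss1 and Aldh1a3 had none within 10 kb, and the peak nearest to Cck lay at 65116 bp. Named genes of both directions stood on each side. Cyp4f39, T2, Sytl3, Ppp1r17, Plek2 and Pyy, which fell, had none within 10 kb. Gast, Vgf, Npy and Nog, which rose, had at least 1.

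**Figure D4:**
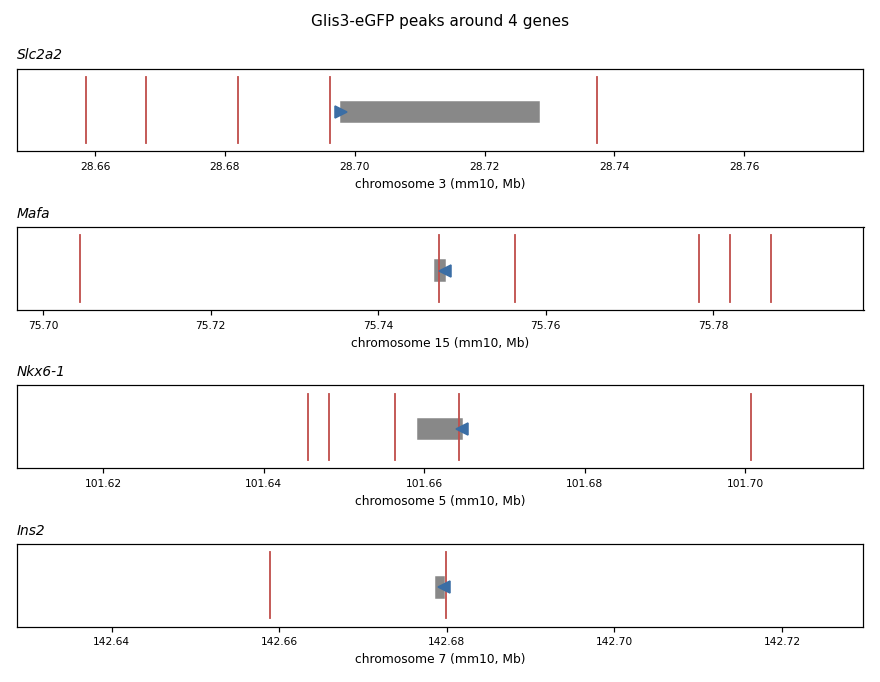
Glis3-eGFP peak midpoints (red lines) around Slc2a2, Mafa, Nkx6-1 and Ins2 in mm10 coordinates (Mb), with the gene span as a grey bar and a blue arrowhead at its 5′ end. Each gene has a peak within 10 kb of its 5′ end, at −1689 bp for Slc2a2 and −170 bp for Ins2.

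Peaks were more common near genes that fell and less common near genes that rose. A peak lay within 10 kb of 688 of the 763 lower genes (90.17%), against 79.95% of all other tested genes (odds ratio 2.30, 95% interval 1.80 to 2.97, 2-sided Fisher's exact test p = 1.1e-13). It lay within 10 kb of 916 of the 1268 higher genes (72.24%), against 81.28% of the others (odds ratio 0.60, 0.53 to 0.69, 2-sided Fisher's exact test p = 9.2e-14). Compared directly, lower genes had 3.52 times the odds of higher genes (2.68 to 4.67, 2-sided Fisher's exact test p = 1.9e-23). Genes are not independent replicates, and peaks follow expression: with mean log2 CPM as a covariate the odds ratio was 1.23 (0.951 to 1.58) for lower genes and 0.34 (0.29 to 0.39) for higher genes. With control log2 CPM as the covariate, which the change itself does not move, the odds ratio was 0.952 (0.736 to 1.23) for lower genes and 0.511 (0.44 to 0.593) for higher genes.

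**Figure D5:**
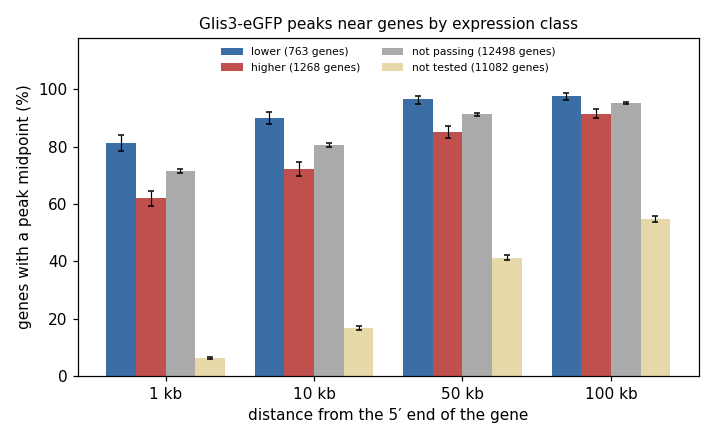
Percent of genes with a Glis3-eGFP peak midpoint within 1, 10, 50 and 100 kb of their 5′ end, for lower, higher, not passing and not tested genes, with exact binomial 95% intervals as error bars. Within 10 kb the shares are 90.17%, 72.24%, 80.73% and 16.76%.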

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

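The tests of library composition, of libraries swapped between groups, of the share of beta cells and of expression level over all libraries were chosen after the results they bear on were seen. Among 122 sets of 4 control values, 5 had a library far from the other 3, where chance gives 6.1. Cd79a stood at 20.5 CPM in control 4 and at 14.5 to 15.1 CPM in the other controls. Edem1 stood at 51 CPM in control 1 and at 67.5 to 70.9 CPM in the others. Sval2 stood at 0.209 CPM in control 1 and at 0 to 0.0194 CPM in the others. Pgc stood at 0.0697 CPM in control 1 and Krt27 at 0.0194 CPM in control 2, with 0 in the other controls for each.

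Glis3 counts were higher, not lower, in the libraries labelled knockout. Library composition would move all genes alike. Scaled by library size alone, Glis3 was at 0.664 (SE 0.194) with the median of all genes at 0.175. With the 10 most abundant genes also left out, Glis3 was at 0.349 (SE 0.152) with that median at −0.155. Glis3 stayed more than 2 SE above the median. The rule for this test also asked for a call, which was not met (edgeR adjusted p = 0.122, with 0.00948 to 0.372 over the alternatives). That p-value is for a change from 0, not from the shifted median. With the rule met only in part, composition stays open. The number of libraries closer on average to the other group than to their own was 0, but labelled knockout 3 was close to even (mean correlation 0.9439 with its own group and 0.9421 with controls), and an exchange of the 2 whole groups would leave that number at 0 too. Against such an exchange, the list of earlier described Glis3 targets was lower (camera adjusted p = 0.0285; adjusted p = 0.457 with an estimated correlation) and distal peaks went with genes that fell (odds ratio 1.95, 1.67 to 2.28) and not with those that rose (0.892, 0.793 to 1), as the labels would have it for an activator, but neither was set as a test of the labels, so mislabelling stays open. A rise of transcripts that lack the deleted exons may also explain the count, and was not tested, and the call itself was lost in 4 of the 7 fits that left out 1 library.

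Ins1 and Ins2 fell, which a smaller share of beta cells in the islets could produce. Against that as the whole cause, Iapp, which beta cells also make in bulk, rose (log2 1.84, SE 0.16). The rule for this test also asked that Gcg, Sst and Ppy move apart. That part was met only through Ppy, at −3.73 (SE 0.42), with Gcg at −0.32 (SE 0.20) and Sst at 0.12 (SE 0.16). The fall of Ppy was seen before the rule was written and does not bear on the share of beta cells. RNA from acinar cells does not account for the fall either, since Ins2 was at −1.64 (SE 0.333, edgeR adjusted p = 0.00857; 3.8e-13 to 0.00857 over the alternatives) with the acinar marker mean as a covariate. Lower insulin transcript levels per beta cell are a candidate explanation, found and tested on the same libraries, and a part played by cell number stays open.

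Peaks lay more often near genes that fell and less often near genes that rose. For lower genes, expression level could account for the difference within 10 kb, since the odds ratio was 1.23 (95% interval 0.951 to 1.58) with mean log2 CPM and 0.952 (0.736 to 1.23) with control log2 CPM as a covariate. With mean log2 CPM it was 2.07 (1.61 to 2.65) with peaks given to the nearest gene, 1.54 (1.03 to 2.32) within 50 kb and 1.26 (1.02 to 1.55) with the DESeq2 calls, but 1.03 (0.848 to 1.26) within 1 kb, 1.2 (0.74 to 1.94) within 100 kb and 1.07 (0.727 to 1.57) at adjusted p under 0.01, so the result depends on how peaks and genes are chosen. For higher genes expression level does not account for the lack of peaks, as the odds ratio was 0.341 (0.294 to 0.395) with mean log2 CPM and 0.511 (0.44 to 0.593) with control log2 CPM as a covariate. Expression of the risen genes in cell types or at an age other than those of the binding experiment stays open and was not tested.

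Of the 35 ways to split the 7 libraries into 4 and 3, 1 gave as many lower genes (763; the highest other split gave 1), 1 as many higher genes (1268; the highest other gave 4) and 1 as many gene lists (11; the highest other gave 10), the real split in each case, under 5% of the splits each time. The other splits gave 3 to 10 lists with almost no called genes, so a number of lists near 11 is not unusual for camera with its preset correlation. The split that follows Xist gave 1 lower and 4 higher genes. Every other split mixed controls and labelled knockouts, with no term for them in the fit, so the group difference added to the spread. Few calls there do not show that differences linked to Xist are small. With a covariate for Xist the real comparison gave 863 lower and 1445 higher genes.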

How the results depend on the processing

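The covariate for Xist and the fit of the libraries with Xist reads were chosen after seeing the data; the cause of each change below was not tested unless stated. Besides Glis3, 83 named genes were called. Of these, 59 kept direction and call under every alternative fitted gene by gene but the Xist libraries, and 53 under that one too. The adjusted p under 0.01 and glmTreat were counted over all genes only. The 763 lower genes became 324 with library size alone, 334 with the acinar covariate, 314 in the Xist libraries (fewer samples), 336 at adjusted p under 0.01 and 138 with glmTreat, and the 1268 higher genes became 718, 734, 731 and 436 in the last 4; the other counts were within 1.5 times. The 11 lists became 0 with an estimated correlation. Glis3 was no longer called with the replicate block (0.48, edgeR adjusted p = 0.0505), the acinar covariate (0.45) or the Xist libraries (0.26; 0.00948 to 0.372 over the alternatives), and ran from 0.42 to 0.64 with 1 library left out. The odds ratio of lower genes was 1.23 with the mean log2 CPM covariate and 0.952 with control log2 CPM. The share of peaks near genes was 49.96%, 82.36% and 90.91% at 1, 50 and 100 kb, by construction. Values that turned were Pdx1 (0.081 with library size alone; −0.21 to 0.064 with 1 library left out) and Srsf6 (0.13 with library size alone, 0.0017 in the Xist libraries). Lists whose test turned had medians of 1.28 without a filter and −1.75 to 1.45 with 1 library left out (lymphocyte), 0.067 with limma-voom, 0.083 with the block, 0.040 in the Xist libraries and −0.24 to 0.48 left out (immediate early), −0.23 with the acinar covariate and −0.095 to 0.29 left out (cell cycle), −0.27 to 0.050 (delta), −0.31 to 0.017 (Gli, Glis and Hedgehog), 0.015 to 0.51 (Schwann and glial), and −0.30 for acinar markers with their own mean as covariate, by construction. Libraries of the same replicate number were at most weakly paired (correlations of deviations 0.126, 0.08 and 0.092). Of 3 labelled knockouts, 2 correlated best with their own number. The replicate block gave 803 lower genes, 1385 higher and 13 lists. In both groups numbers 1 and 2 had Xist reads and number 3 had Y-linked reads, so the block also takes up that split. Sst passed with library size alone (0.32, edgeR adjusted p = 0.0416; 0.0416 to 0.963 over the alternatives). Alternatives on peak scores and motifs were not run. In simulated data with 98 calls, 12.5% of changes of 1.5-fold were found. The real comparison had many more calls, which loosens the adjusted threshold, so that share does not carry over to it.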

Other observations

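The abundant genes named in this paragraph and the control log2 CPM fit for distal peaks were chosen after values were seen. Among the 35 genes with a mean of at least 1000 CPM, 6 were lower and 19 higher in the libraries labelled knockout. Gnas, which encodes the stimulatory G protein alpha subunit, rose from 2230 to 10983 CPM (log2 2.30, SE 0.14, edgeR adjusted p = 3.7e-07), and Pappa2, a protease gene that acts on insulin-like growth factor binding proteins, rose from 223 to 2150 CPM (log2 3.27, SE 0.16, edgeR adjusted p = 6.0e-08). The granin gene Scg2 (log2 0.99) and the prohormone processing enzyme genes Pcsk2 (0.75) and Cpe (0.86) rose, as did the protein disulfide isomerase genes Pdia3 (0.89) and P4hb (0.62), while Ero1lb, which encodes an oxidase of the endoplasmic reticulum in beta cells, fell by 0.61 (SE 0.15).

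The fixed gene lists differed in how many of their tested members had a Glis3-eGFP peak within 10 kb, against 80.49% of all tested genes. Peaks lay near 5 of 34 acinar markers (2-sided Fisher's exact test, adjusted p = 6.0e-15), 2 of 18 stromal and pericyte markers (5.7e-09), 6 of 17 endothelial markers (5.1e-04), 2 of 8 gamma and epsilon cell markers (0.00696), 6 of 14 alpha cell markers (0.00927) and 8 of 17 macrophage markers (0.00927). They lay near all 22 genes of the unfolded protein response (adjusted p = 0.0501), 27 of 28 of oxidative phosphorylation (0.0783), all 16 immediate early and heat shock genes (0.106) and 23 of 26 islet transcription factors (0.567), shares that did not pass, as did 18 of 27 beta cell identity genes (0.149). These counts are not matched for expression level.

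A hypothesis set before its test was that peaks away from gene starts follow the genes that changed. Of the 10636 peaks more than 1 kb from every 5′ end, at least 1 lay within 50 kb of 65.7% of lower genes, against 46.2% of other tested genes (odds ratio 2.23, 95% interval 1.91 to 2.61), and the odds ratio was 1.95 (1.67 to 2.28) with mean log2 CPM as a covariate. For higher genes the shares were 47.4% and 47.2%, with an odds ratio of 1.01 (0.897 to 1.13), or 0.892 (0.793 to 1) with the covariate. With control log2 CPM as the covariate, a fit chosen after these values were seen, the odds ratios were 1.86 (1.59 to 2.18) for lower and 0.972 (0.865 to 1.09) for higher genes. If the labels are right, binding away from gene starts may mark genes that depend on Glis3 for their level. The same odds ratios were set above against an exchange of the groups, so these readings are not independent. Other islet regulators bound at the same sites could give the same result and were not tested, and the peak list had no replicate.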
